A study of Mus musculus with 4 samples.

How the data were processed

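Single-cell RNA sequencing was carried out on tracheal cells of adult mice on the 129S6/SvEvTac background. Per the labels, the 4 samples were wild-type mice and 3 mutant lines with primary ciliary dyskinesia: bgh mice with a mutated Spef2, Cfap54gt/gt mice with a gene trap in Cfap54, and nm1054 mice, which lack Cfap221. Each sample was 1 library of cells pooled from 6 tracheas, or 5 for bgh, from mice aged 5 to 8 months. Per the labels' protocols, tracheas were digested with pronase, the cells were plated to separate fibroblasts, dead cells were removed, and 8500 cells were loaded for a target of at least 5000. Plating and dead-cell removal can set the shares of cell types that reach a library.

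The deposited matrix held raw counts of unique molecular identifiers (UMIs) per gene and cell barcode for all 4 libraries together. Per the file headers, it was written by Cell Ranger 6.0.1, and per the submitters' processing notes, Cell Ranger and the mouse build GRCm39 were used. The gene annotation release was not given in the sources used here. The matrix held 21667 barcodes and 22583 features, of which 4747 had 0 UMIs in every barcode. Its barcodes ended in a library number from 1 to 4. No source used here tied a number to a genotype, so the libraries are called by number and the planned comparison of mutant with wild-type cells was not made. A genotype was never read from the values. Gene symbols came from the deposited feature table, and 22 symbols were shared by more than 1 feature.

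Libraries 1 to 4 held 4269, 4202, 7360 and 5836 barcodes with 44520016, 39658153, 53491773 and 47459846 UMIs. Barcodes had 500 to 54154 UMIs, so the minimum of 500 UMIs removed none. Cells with under 300 genes or over 20% mitochondrial UMIs were left out, which removed 1308 barcodes and left 20359. Doublets were scored in each library from 2 simulated doublets per cell. An automatic threshold marked 0.133% of cells, which was taken as a failure. After that was seen, the highest-scoring cells of each library were removed up to the rate expected from loading, 0.8% per 1000 cells. That rule took 116, 125, 410 and 237 cells and left 3692, 3830, 6746 and 5203. Of the barcode sequences, 52 occurred in more than 1 library, and such barcodes were kept as separate cells.

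Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken over all libraries, and cells were clustered by the Leiden method on 15 neighbours at resolution 1. Clusters were named from 32 lists of cell type markers. A marker counted where it was detected in at least 10% of a cluster's cells and lay at least 1 log2 unit above the 25th percentile over clusters, with 5 CPM (a gene's summed UMIs scaled to a common total per sum) added. A name needed 3 markers, and the class with the highest mean over its markers was taken. A cluster was called mixed where a class of another lineage had at least 75% of its markers up. For this rule, basal, secretory, goblet, gland, hillock and alveolar type 2 classes were 1 lineage, as were ciliated with deuterosomal and neuroendocrine with neuron classes, and proliferating cells were exempt. Clusters with more markers of another class than of their own among their top 10 genes, and shallow clusters with none of their own there, stayed unnamed unless they were mixed. The markers were fixed before the data were examined, and this scoring rule was set afterwards. Names are therefore given as X-like, and free RNA in droplets was not subtracted.

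Comparisons used UMIs summed per library and class and expressed as CPM. Ciliated-like cells were compared with the other named epithelial classes of the same library. Secretory-like, basal-like and macrophage-like cells were each compared with all other filtered cells of the same library. Ratios were log2 values with a pseudocount of 1 CPM, and a direction was counted only where all 4 libraries had it. If each direction were equally likely, 12.5% of genes would have the same direction in 4 of 4 libraries. There were 23 fixed gene lists with 378 genes, of which 7 were not measured. Listed genes that were also cell type markers were left out of all list counts, medians, sums and percentiles. Foxj1, Myb, Mcidas, Gmnc and Ccno were thus left out of the transcription factors, and Ltf, Bpifa1, Bpifb1, Bpifb2, S100a8 and S100a9 out of secreted defence. A list's median was also placed among 10000 random lists of the same size matched on mean expression in 20 bins, over members with at least 50 UMIs, as a description of these libraries. Between libraries, genes with at least 100 UMIs in a class of at least 100 cells per library were ranked by highest over lowest CPM, with a library under 3 UMIs set to 3 UMIs. A gene was counted as apart where that ratio was at least 2 and the 95% intervals did not overlap. Intervals were exact Poisson for CPM and Clopper-Pearson for shares. They cover counting error only, since each genotype had 1 library and no replicate. No p-value was computed.

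Named genes followed a rule fixed before the data were examined: the targeted genes Cfap221, Spef2 and Cfap54; per list, among members with at least 50 UMIs and the same direction in every library, the 3 with the largest and the 2 with the smallest log2 ratio; and between libraries, the 10 non-marker genes with the largest ratio and the most variable member of each list where its ratio was at least 2. Only some of the genes that the rule takes are printed. A few genes outside it are named as chosen after their values were seen.

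The alternatives fixed before the data were examined were 1000 UMIs per cell, at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, variable genes chosen within each library, a pseudocount of 10 CPM, cells thinned to 500 UMIs, list members with at least 50 UMIs only, means over cells, a floor of 10 UMIs, at least 400 UMIs, and TMM scaling. The alternatives chosen after seeing the data were clustering without the listed genes, ciliated-like clusters with a median of at least 3000 UMIs only, and leaving out each library in turn. Code was tested on simulated counts drawn from the real means and library sizes with 200 altered genes. Genes above 1000 CPM were not altered, since altering them shifts all other CPM values. In the step on 12630 genes, 93% of 2-fold and 100% of 4-fold higher genes in ciliated-like cells were called higher in all 4 libraries. In the steps on 13157 genes, these shares were 100% and 100% for secretory-like, 97% and 100% for basal-like, and 12% and 40% for macrophage-like cells. Of unaltered genes, 4.08%, 3.43%, 4.18% and 1.37% were called higher in ciliated-like, secretory-like, basal-like and macrophage-like cells, and 9.85%, 13.0%, 9.59% and 39.0% lower. All simulated 3-fold and 8-fold differences between libraries were called, 100 of each per class, as were 27 of 8938 unaltered genes in ciliated-like, 15 of 9766 in secretory-like and 27 of 8491 in basal-like cells. Clustering split 1600 simulated cells of 4 classes into 7 clusters and placed 1600 of 1600 in a cluster led by their class. These cells were drawn from mean profiles of classes that the same clustering had formed. The step therefore checks the code and not the classes. Neighbouring genes were taken from a gene table of GRCm38.p6, another build, so no coordinates are given. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.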

Results

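Single-cell transcriptomes were collected from the tracheas of wild-type mice and of 3 mouse lines with primary ciliary dyskinesia, a disease of motile cilia. The mutated genes, Cfap221, Spef2 and Cfap54, encode proteins of the central pair apparatus, the structure at the centre of the motile axoneme. Each of the 4 groups was 1 library from pooled tracheas, so no value had a biological replicate. The counts were unique molecular identifiers (UMIs) from 3' tags. Libraries 1 to 4 held 44520016, 39658153, 53491773 and 47459846 UMIs, with medians of 6780, 6310.5, 5734.5 and 6172.5 UMIs per barcode. After filtering, 3692, 3830, 6746 and 5203 cells were kept. The library numbers could not be tied to genotypes from the sources used here. Values are therefore given for each numbered library, and mutant and wild-type cells were not compared.

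The tracheal cells fell into 3 large epithelial classes and several small ones. Secretory-like cells, led by Scgb1a1, Scgb3a1 and Bpifb1, made up 32.1% of all filtered cells, basal-like cells, led by Krt5, Krt14 and Apoe, 25.4%, and ciliated-like cells, led by Ccdc153, Tmem212 and Dynlrb2, 24.2%. Hillock-like cells with Krt13 and Krt4 made up 2.69%, tuft-like cells 0.781%, proliferating-like cells 0.611%, neuroendocrine-like cells 0.216%, T cell-like cells 0.205% and macrophage-like or monocyte-like cells 0.180%. Mixed clusters, which carried markers of more than 1 lineage, held 11.9% of cells, and 1721 of these cells formed a cluster with ciliated and secretory markers together. Other mixed clusters held 225 cells with 9 of 9 tuft markers up, 193 with 8 of 8 neuroendocrine markers and 57 with 6 of 6 ionocyte markers. A further mixed cluster of 103 cells had 5 of 7 deuterosomal markers up. The shares of the small classes leave out all these cells.

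Across libraries 1 to 4, ciliated-like cells made up 32.0% (95% Clopper-Pearson interval 30.5 to 33.5), 25.9% (24.5 to 27.3), 18.6% (17.7 to 19.6) and 24.6% (23.4 to 25.8) of filtered cells. Secretory-like shares were 28.4%, 31.2%, 34.1% and 32.6%. Basal-like shares were 19.4%, 25.7%, 27.3% and 26.9%, and hillock-like shares 1.54%, 1.17%, 3.32% and 3.79%. Mixed clusters held 10.0%, 13.7%, 14.0% and 9.09%. An unnamed shallow cluster with a median of 636 UMIs held 7.07% of library 1 and 1.07%, 0.119% and 0.846% of libraries 2 to 4. These shares can also carry effects of plating and dead-cell removal, which were not tested, and of depth, since ciliated-like cells had a median of 2484 UMIs against 10788.5 in secretory-like and 4022.5 in basal-like cells.

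**Figure D1:**
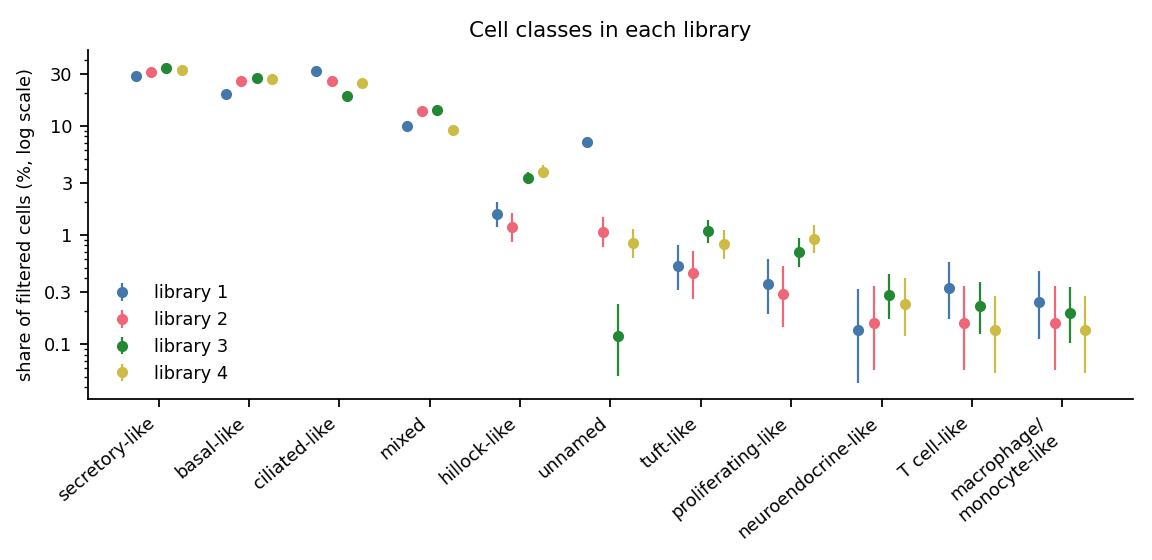
Share of filtered cells in each class (%, log scale) for libraries 1 to 4, with points for the shares and bars for 95% Clopper-Pearson intervals, which cover counting error only. Ciliated-like shares ran from 18.6% in library 3 to 32.0% in library 1, and the unnamed class reached 7.07% in library 1.

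The genes mutated in the 3 lines were measured in ciliated-like cells, to give the level of each in every library. Cfap221 (ENSMUSG00000036962) had 76, 42, 0 and 51 UMIs in libraries 1 to 4, which gave 11.3 CPM (95% Poisson interval 8.91 to 14.2), 13.2 CPM (9.50 to 17.8), 0 CPM and 11.2 CPM (8.31 to 14.7). The 0 UMIs in library 3 had a 95% Poisson upper limit of 0.990 CPM. With library 3 set to 3 UMIs, or 0.805 CPM, Cfap221 was 16.4-fold lower there than in library 2. Dbi and 2 further genes next to Cfap221 also had 0 UMIs in library 3. Cfap54 (ENSMUSG00000020014) had 13 UMIs in library 2, or 4.08 CPM (2.17 to 6.98), against 104 (96.8 to 112), 119 (109 to 131) and 120 CPM (110 to 130) in libraries 1, 3 and 4. Spef2 (ENSMUSG00000072663) was at 150 CPM (141 to 160) in library 1 and at 243 (226 to 261), 254 (238 to 270) and 247 CPM (232 to 261) in libraries 2 to 4. No genotype was assigned to a library from these values. A kept level does not show an unaltered gene, since a mutation can leave the 3' end of a transcript in place. That limit does not bear on a loss of tags, as for Cfap221 in library 3 and Cfap54 in library 2. Per the labels, nm1054 mice lack Cfap221, but no label ties a library number to a genotype.

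In basal-like cells, which lack motile cilia, Cfap221 had 0 UMIs in all 4 libraries, allowing at most 0.627 CPM at 3 UMIs. Spef2 was at 0.288 to 1.16 CPM there and Cfap54 at 0 to 0.288 CPM. Spef2 was detected in 52.6%, 47.3%, 44.8% and 48.7% of ciliated-like cells, Cfap54 in 35.8%, 1.31%, 24.3% and 29.3%, and Cfap221 in 6.19%, 4.14%, 0% and 3.91%. At most 0.418% of basal-like cells of any library held a UMI of these genes, although their median depth of 4022.5 UMIs exceeded the 2484 of ciliated-like cells. Median depth of the ciliated-like cells differed between libraries, at 3729, 2254, 2036 and 2407.5 UMIs. Their deepest cluster, with a median of 7314 UMIs, supplied 63.6%, 45.3%, 62.1% and 54.6% of the class's UMIs. In the ciliated-like clusters with a median of at least 3000 UMIs, a subset chosen after seeing the data, Cfap221 in library 2 was at 8.32 CPM, Cfap54 in library 2 at 2.08 CPM and Spef2 in library 1 at 100.2 CPM. Averaged over cells in place of summed, Cfap54 in library 2 was at 7.13 CPM.

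**Figure D2:**
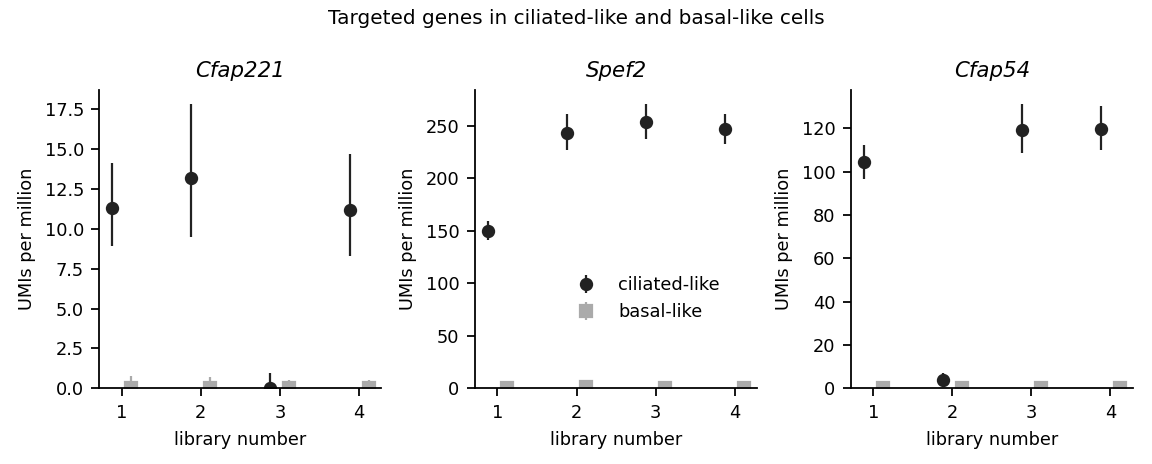
CPM of Cfap221, Spef2 and Cfap54 in ciliated-like cells (circles) and basal-like cells (squares) of libraries 1 to 4, with 95% Poisson intervals for counting error. Cfap221 was at 0 in library 3 and Cfap54 at 4.08 CPM in library 2, while Spef2 ran from 150 to 254 CPM in ciliated-like cells.

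Ciliary genes were compared as groups between libraries within ciliated-like cells. The 17 central pair genes, which include the 3 mutated genes, summed to 1407, 1607, 1864 and 1829 CPM in libraries 1 to 4, and the 15 radial spoke genes to 2321, 2630, 2940 and 2917 CPM. Outer dynein arm genes summed to 768, 911, 1103 and 981 CPM and intraflagellar transport genes to 2605, 3030, 3242 and 3227 CPM. Library 1 was lowest for each of these groups, by at most 1.44-fold. Relative to 1000 UMIs of the other central pair genes, a scale chosen after the values were seen, Spef2 had 131 UMIs in library 1 and 181, 170 and 170 in libraries 2 to 4. Cfap54 had 3.03 UMIs in library 2 on that scale and 91.4, 80.1 and 82.4 in libraries 1, 3 and 4. In the same cells, secreted defence genes summed to 25756, 15250, 12243 and 24892 CPM, of which Reg3g alone made up 20717, 8433, 6258 and 18771 CPM, and mucin genes to 943, 362, 414 and 691 CPM.

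Ciliated-like cells were set against the other epithelial classes of the same library to see which fixed gene groups they carried. The UMIs of those classes were summed, with 76403107 from secretory-like and 23586666 from basal-like cells, so the ratios mostly reflect secretory-like cells. Genes of the ciliary axoneme were far higher in ciliated-like cells in all 4 libraries. For the central pair apparatus, 16 of 17 genes were higher in each library, with a list median log2 ratio of 5.66. The exception was Cfap221, with 169 UMIs in ciliated-like cells and 1 UMI in the other epithelial cells, which had 0 UMIs in both classes of library 3. Spef2 reached 7.04 (6.82 to 7.27 over libraries), Spag17 and Spag6l 6.81 each, Stk36, a kinase needed for the central pair, 4.96, and Cyb5d1 2.80. All 15 radial spoke genes were higher (median 5.58), from Rsph1 at 7.58 and Cfap206 at 7.19 down to the close paralogs Rsph3a and Rsph3b, whose split of reads is uncertain. All 10 outer arm genes (5.61) were higher, with the heavy chain Dnah5 at 6.94 and the intermediate chain Dnai2 at 6.51. All 16 inner arm and nexin link genes (6.11) were higher too, with Dnali1 at 7.56 and Ccdc39 at 7.28.

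The genes that build these structures were also higher in ciliated-like cells. All 11 dynein assembly factors were higher in each library (median 4.55), with Zmynd10 at 6.39 and Spag1 at 2.79. All 21 intraflagellar transport genes were higher (4.0), with Ift172 at 5.59 and Ift20 at 1.33. Ttc21b, at 0.86, was at -0.02 once cells were thinned to 500 UMIs. Of 5 ciliogenesis transcription factors outside the marker lists, 3 were higher in each library. They were Rfx3 at 4.15, Rfx2 at 4.01 and Trp73 at 3.64. Of 14 tubulins and tubulin modifiers, 11 were higher, with Tuba1a at 5.86 and the ligase Ttll9 at 5.00, and 2 were lower, Tubb5 at -0.86 and Tuba4a at -0.90. The medians of the central pair, radial spoke, dynein arm, assembly, transport and tubulin lists lay at percentile 100 of 10000 matched random lists, and that of the transcription factors at percentile 99.85 on 4 genes.

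Defence and stress genes in ciliated-like cells differed by group. As a reference, 12630 background genes with at least 50 UMIs had a median log2 ratio of 0.50 in this comparison, and 59.4% of them were higher in all 4 libraries. A share of list members near 59.4% does not set a list apart. The list counts also include members with fewer UMIs, so they are not on the same footing as that share. For antigen presentation, 12 members had at least 50 UMIs. Of 26 interferon response genes, 21 were higher in each library (median 1.23), among them Oasl2 at 3.80, the deubiquitinase Usp18 at 3.72 and Ifit3, which has a close copy and an uncertain count, at 3.45, while Gbp2 at -1.29 and Ifi27l2a at -2.66 were lower. Of 17 antigen presentation genes, 10 were higher, including H2-K1, a classical class I molecule, at 1.10. H2-T23, at 0.21, was at -0.17 after thinning. Of 15 secreted defence genes, 11 were lower, including the protease inhibitor Slpi at -4.82 and complement C3 at -4.34, and 2 were higher, Chia1 at 4.35 and the lectin Reg3g at 1.63 (0.63 to 1.87). Reg3g was also abundant in secretory-like cells. Of 11 mucin-related genes, 8 were lower, with Muc5b at -5.22, and the lectin Itln1 was higher at 3.49. Of 29 cytokines, 15 were lower, with the neutrophil chemokines Cxcl1 at -3.12 and Cxcl2 at -3.71, and 2 were higher, including Cxcl17 at 1.37. Of 17 glutathione and oxidative stress genes, 11 were higher, with the peroxiredoxin Prdx6 at 1.63 and Gclc, the catalytic unit of glutathione synthesis, at 1.44. Xenobiotic genes were split, 7 higher and 9 lower of 20, with Nqo1 at 2.45 and Ces1f at -4.86. Over members with at least 50 UMIs, the list medians lay at percentile 99.34 of matched random lists for interferon response, 91.98 for antigen presentation, 99.46 for glutathione, 10.55 for xenobiotic genes and 0 for secreted defence, mucin-related genes and cytokines.

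Among 13 Notch pathway genes, 8 were higher in ciliated-like cells, led by Lfng at 4.07 and Hes1 at 2.06, and Dll1 was lower at -2.27. Summed Notch genes were at 513, 548, 572 and 742 CPM in ciliated-like cells of libraries 1 to 4. In basal-like cells they were at 513, 476, 538 and 499 CPM, and in secretory-like cells at 89.0, 88.6, 101 and 98.7 CPM. The higher ratios thus largely reflect low levels in secretory-like cells. Jag1, at 0.37, was at -0.63 after thinning. Of 13 wound repair and keratin genes, 8 were lower, with Krt17 at -4.61, and Hbegf was higher at 1.37. Ion transport genes were 4 higher and 6 lower of 12, with Slc9a3r1 at 2.12 and the chloride channel Ano1 at -3.22. Matrix genes were 4 higher and 8 lower of 16, with Col4a1 at 2.15 and Col17a1 at -3.61. Of 14 macrophage activation genes, 6 were lower, with Apoe at -4.82. Immediate early and heat shock genes, which dissociation can induce, were higher for 14 of 17, with Fos at 3.62 and Ier2 at 2.39. RNA quality genes were 2 higher and 1 lower of 8, with mt-Co1 at 0.40. Percentiles among matched random lists were 56.7 for Notch, 20.55 for ion transport and 32.68 for RNA quality, 0 for wound repair and for matrix, 0.09 for macrophage activation, and 100 for immediate early and heat shock genes. Of 12630 background genes with at least 50 UMIs, 59.4% were higher in all 4 libraries and 19.8% lower. The listed genes took part in forming the classes, since 168 of the 2000 variable genes were listed genes without a marker role.

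**Figure D3:**
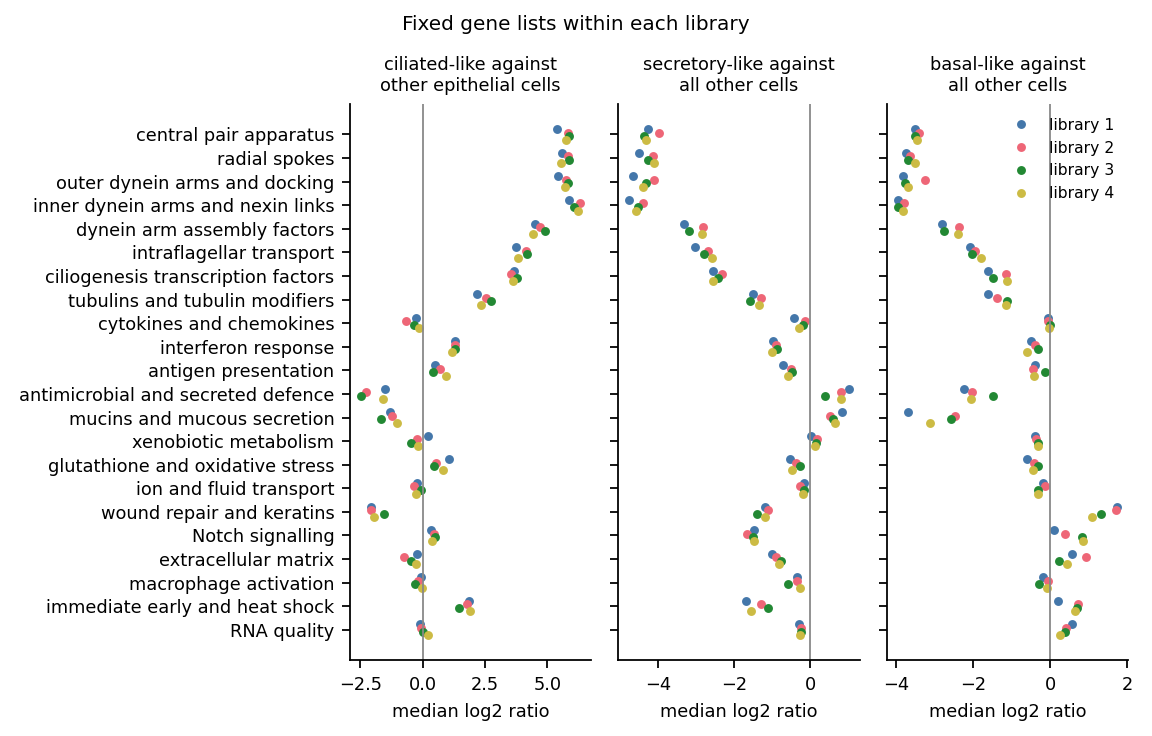
Median log2 ratio of each fixed gene list within libraries 1 to 4, with 1 point per library, for ciliated-like cells against other epithelial cells, secretory-like cells against all other cells and basal-like cells against all other cells. Ciliary lists lay above 0 in ciliated-like cells and below 0 in the other classes, secreted defence lay above 0 in secretory-like cells, and wound repair and keratins lay above 0 in basal-like cells.

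Secretory-like cells were compared with all other filtered cells of each library for the same gene groups. The other cells included the mixed clusters, with 42760685 UMIs and secretory markers in their largest cluster, which can dilute the ratios. In ciliated-like cells, the median of the central pair list was 3.23 against all other cells and 5.66 against the other epithelial classes, which leave out mixed clusters. Secreted defence genes were higher for 9 of 15 members in all 4 libraries, with lysozyme Lyz2 at log2 1.21 (0.86 to 1.54), the siderophore-binding Lcn2 at 1.06 (0.14 to 1.65) and the collectin Sftpd at 1.05. Lyz2 shares close sequence with Lyz1, so its count is uncertain. Mucin-related genes were higher for 8 of 11, with the gel-forming mucin Muc5b at 1.38, Clca1 at 1.20 and Muc1 at 1.12. Xenobiotic genes were higher for 9 of 20 and lower for 6, with the carboxylesterase Ces1f at 2.01 and Fmo1 at 1.19. Over members with at least 50 UMIs, the medians of these lists were 0.88, 0.65 and 0.17, each at percentile 100 of matched random lists.

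Other groups were mostly lower in secretory-like cells, as were most genes. Over 13157 background genes with at least 50 UMIs, the median log2 ratio was -0.63. Medians over such members lay above it for RNA quality (-0.25), cytokines (-0.28), ion transport (-0.37), glutathione (-0.49) and antigen presentation (-0.59). They lay below it for the interferon, Notch, wound repair, matrix, macrophage activation, immediate early and ciliary lists. Cytokines were higher for 3 of 30, with Cxcl15 at 1.40 and the neutrophil chemokine Cxcl5 at 1.20, and lower for 13, with Cxcl10 at -1.84. Ion transport genes were higher for 4 of 12, with Scnn1b, a sodium channel subunit, at 0.87 and Ano1 at 0.75, and lower for 7. Glutathione genes were higher for 3 of 17, with the cystine transporter Slc7a11 at 0.57, and lower for 11, with Gclc at -0.91. Interferon genes were lower for 22 of 26, with Usp18 at -2.96, and antigen presentation genes for 15 of 17. Notch genes were lower for 12 of 13, with Jag2 at -3.42 and Lfng at -3.76. Wound repair and keratin genes were lower for 11 of 13, with Krt17 at -2.62, and matrix genes for 13 of 16, with Col17a1 at -4.08. Macrophage activation genes were lower for 9 of 14, with Apoe at -5.98, and Retnla was higher at 1.60 (0.20 to 3.48). Immediate early and heat shock genes were lower for 14 of 17, with Fos at -3.24, and the heat shock gene Hspa1a, whose count is uncertain beside its copy Hspa1b, was higher at 0.86. RNA quality genes were lower for 8 of 8 (median -0.25). Ciliary lists were lower, with 16 of 17 central pair genes (median -4.23) and 21 of 21 transport genes (-2.70), while the tubulins Tuba4a at 0.34 and Tubb2a, uncertain beside Tubb2b, at 0.32 were higher. Of 13157 background genes, 86.3% were lower in secretory-like cells and 3.60% higher, and among matched random lists the medians of cytokines lay at percentile 99.97, RNA quality at 95.06, ion transport at 92.13, antigen presentation at 63.64, glutathione at 50.69, macrophage activation at 18.96 and interferon response at 2.67. The 8 secretory markers alone summed to 240517 to 261420 CPM over all filtered cells of a library. In secretory-like cells, Scgb1a1 was at 196989, 160041, 153200 and 144381 CPM in libraries 1 to 4, which leaves a smaller share for all other genes.

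In basal-like cells, wound repair and squamous keratin genes were higher for 9 of 13 members in all 4 libraries and lower for none. The cornified envelope protein Ivl was at log2 4.10 (3.43 to 4.79), the keratin Krt17 at 3.57, Sprr1a at 3.20, the growth factor Ereg at 1.25 and Hbegf at 0.57. Notch genes were higher for 7 of 13, with the ligands Dll1 at 4.10, Jag2 at 2.26 and Jag1 at 2.19, and Lfng was lower at -1.18. Nrarp, at 0.25, was at -1.17 after thinning. Matrix genes were higher for 9 of 16, with the hemidesmosome collagen Col17a1 at 4.28 and the laminin chains Lamb3 at 4.16 and Lama3 at 2.89, while Lama5 was lower at -0.93. Over members with at least 50 UMIs, the medians of these lists were 1.70, 1.17 and 0.67, at percentiles 100, 99.93 and 99.75 of matched random lists.

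Cytokines in basal-like cells were split, 9 higher and 11 lower of 30, with Cxcl10 at 3.06, Cxcl1 at 2.83 and Ccl20 at 2.79 against Cxcl17 at -2.97. Macrophage activation genes were 3 higher and 6 lower of 14, with the lipoprotein Apoe, a leading gene of this class, at 6.52 and Tgfb1 at 2.65. Secreted defence genes were lower for 12 of 15, with the antibody transporter Pigr at -4.70, and the defensin Defb1 was higher at 5.41. Mucin-related genes were lower for 10 of 11, with Muc5b at -5.92, and Clca2 was higher at 2.41. Xenobiotic genes were 5 higher and 10 lower of 20, with Fmo2 at 1.92 and Cyp2a5, uncertain beside a close copy, at -4.01. Glutathione genes were 3 higher and 12 lower of 17, with the regulator Nfe2l2 at 0.83 and Srxn1 at -1.73. Ion transport genes were 4 higher and 6 lower of 12. Interferon genes were 2 higher and 14 lower of 26, with Gbp2 at 1.88 and Oasl2 at -2.15, and 11 of 17 antigen presentation genes were lower. Irf9, at 0.31, was at -0.43 after thinning, and Igtp, at -0.20, was at 0.08. Immediate early and heat shock genes were 9 higher and 6 lower of 17, with Egr1 at 2.28 and Hsph1 at -1.94, and 7 of 8 RNA quality genes were higher (median 0.40). Central pair genes were lower for 16 of 17 (-3.48). Of 13157 background genes with at least 50 UMIs, 40.9% were higher and 34.0% lower. Percentiles among matched random lists were 95.34 for immediate early and heat shock genes, 59.42 for RNA quality, 4.73 for interferon response, 1.66 for antigen presentation and 0.19 for cytokines.

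Macrophage-like or monocyte-like cells were few, with 9, 6, 13 and 7 cells and 125998 UMIs over the 4 libraries. The class was led by class II antigen presentation genes, with 769 UMIs of H2-Aa, 716 of H2-Eb1 and 677 of H2-Ab1, or 6103, 5683 and 5373 CPM. The chemokine Ccl4, with 192 UMIs and 1524 CPM, the complement gene C1qb and the mast cell protease Mcpt2, known from different immune cells, were also among its leading genes. Against all other cells, 12 of 17 antigen presentation genes were higher in all 4 libraries, with the class I genes H2-D1 at log2 1.29 and H2-K1 at 0.90. Of 30 cytokines, 5 were higher, including Ccl3 at 675 CPM and the inflammatory cytokine Il1b at 476 CPM. Of 14 macrophage activation genes, 4 were higher, including the elastase Mmp12 at 325 CPM. Of 26 interferon genes, 3 were higher, including Bst2 at 2.46 and Ifi27l2a at 1.79. Prdx1 was higher at 1.62. In simulated data 40% of 4-fold higher genes were found in this class and 39.0% of unaltered genes came out lower in all 4 libraries, so lower values were not read. After thinning to 500 UMIs per cell, 13 listed genes in place of 26 were higher in all 4 libraries. Tgfb1 was then at -4.0 against 2.95 and Gbp3 at -1.40 against 4.73, and clustering without the listed genes gave no such class.

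Genes that differed between libraries within a class were then counted, without reference to genotype. In secretory-like cells, 973 of 9984 genes differed at least 2-fold between the highest and lowest library with intervals apart, in basal-like cells 736 of 8679, and in ciliated-like cells 591 of 9150. Dbi, which encodes an acyl-CoA-binding protein, had 0 UMIs in library 3 in all 3 classes. In ciliated-like cells, libraries 1, 2 and 4 had 292, 338 and 277 CPM of Dbi. With library 3 set to 3 UMIs, Dbi was 419.8-fold lower there than in library 2. In ciliated-like cells, Plac9a, which has a close paralog and is uncertain, was at 22.5, 239, 699 and 11.6 CPM. The membrane mucin Muc4 was at 225, 39.5, 99.0 and 163 CPM in libraries 1 to 4, Nqo1 at 24.0, 3.77, 4.56 and 18.2 CPM, and Fosb at 303, 292, 350 and 661 CPM. Among the ciliary lists, Cfap221 and Cfap54 were the genes at least 2-fold apart with intervals apart over all ciliated-like cells, while in the deeper ciliated-like clusters Spef2 ran from 100.2 CPM in library 1 to 248 CPM in library 3.

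In secretory-like cells, Lcn2 was at 163, 22.9, 49.6 and 91.3 CPM in libraries 1 to 4, Retnla at 67.9, 16.1, 12.4 and 12.8 CPM, and Aqp5, a water channel, at 432, 398, 526 and 877 CPM. The cytochrome Cyp2b10 was at 46.5, 89.6, 115 and 39.4 CPM and the drug efflux pump Abcb1b at 1.49, 21.7, 4.78 and 0.792 CPM. Fosb was at 30.3, 39.8, 113 and 84.0 CPM. Over all filtered cells, goblet markers, Tff2 among them at 303, 94.4, 80.4 and 1603 CPM in secretory-like cells, summed to 198, 83.4, 81.4 and 1286 CPM, and erythroid markers to 1.24, 0.135, 0.656 and 70.1 CPM. In basal-like cells, Sprr1a was at 2085, 3814, 2063 and 695 CPM, the matrix protein Tnc at 17.8, 12.2, 5.38 and 4.32 CPM, and the heme oxygenase Hmox1 at 515, 645, 565 and 282 CPM. A basal-like cluster with Sprr1a among its leading genes held 37.8%, 38.2%, 35.2% and 23.8% of the class's cells and another cluster 27.9%, 26.5%, 41.1% and 46.8%, so these values can also carry the make-up of the class. Secretory-like cells had medians of 16043, 11933, 8189.5 and 10774.5 UMIs, and 1 of their clusters held 15.9%, 15.7%, 35.9% and 19.7% of the class's UMIs. Without library 1, 2, 3 or 4 the counts of genes apart were 623, 545, 526 and 532 in secretory-like, 482, 418, 439 and 259 in basal-like and 295, 386, 303 and 376 in ciliated-like cells, and with at least 400 UMIs per gene 381, 217 and 184.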

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

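All tests in this part were chosen after the result was seen, except the comparison of Reg3g with 8 secretory markers and the search for genes above both parent classes in mixed cells, which were written beforehand.

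The feature eGFP, a fluorescent reporter that no label mentions, had 15347 UMIs in library 1, 5304 in library 2, 0 in library 3 and 16333 in library 4. It was among the 10 genes with the largest ratio between libraries in ciliated-like, secretory-like and basal-like cells. In ciliated-like cells it was at 1360, 95.4, 0 and 1973 CPM, and in 91.4%, 22.9%, 0% and 91.9% of cells. In secretory-like cells it was at 2.87, 125, 0 and 5.00 CPM, and in 4.10%, 71.5%, 0% and 5.42% of cells. In basal-like cells it was at 5.64, 221, 0 and 10.1 CPM, and in 2.09%, 56.9%, 0% and 4.65% of cells. In mixed clusters it was in 87.6%, 83.1%, 0% and 84.6% of cells. The 0 UMIs in library 3 had a 95% Poisson upper limit of 0.990 CPM in ciliated-like cells.

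Cfap221, Tmem37, Dbi and 3110009E18Rik had 0 UMIs in library 3 over all barcodes, against 122, 93, 7776 and 140 UMIs in library 1. Low depth was argued against by the UMIs expected there from the other libraries, of which the lowest was 128 for Cfap221 and the highest 9151 for Dbi. Missing cell types were argued against by Dbi, with at least 1108 UMIs expected in each of the ciliated-like, secretory-like and basal-like classes of library 3. On either side in the gene order of GRCm38.p6, Steap3 had 1 UMI in library 3 against 11.8 expected and Tmem177 27 against 61.0, and the next genes, Insig2 and Ptpn4, had 2030 against 1940 and 410 against 482. The stretch was marked out from Cfap221 for as long as library 3 had 0 UMIs, so the 0 measured genes with UMIs within it test nothing. A search of all features, made without gene order, asked for 0 UMIs in 1 library and at least 20 in each other library. In library 3 it found 5 features, eGFP and these 4 genes. Their places side by side are what a difference at 1 place in the genome of those animals, such as a deletion, would give. No genotype was read from them, no other check of such a difference was made, and the counts do not show its extent.

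Reg3g, an antibacterial lectin known from secretory cells, was at 20717, 8433, 6258 and 18771 CPM in ciliated-like cells of libraries 1 to 4, against 9183, 4492, 5536 and 7326 CPM in secretory-like cells. RNA of secretory-like cells counted in ciliated-like cells was weighed as a source, and a small part of the level may come from it. In the test written beforehand, Reg3g's ratio of ciliated-like to secretory-like level had to exceed that of all 8 secretory markers by over 2-fold, and its lowest value was 0.773 times the highest marker ratio, so that test did not exclude it. The marker with the highest ratio was itself 1.27 to 1.68 times as high in ciliated-like cells, which RNA from secretory-like cells cannot give. Scgb1a1, an abundant secretory product, had a ratio of at most 0.0327 against 1.13 to 2.56 for Reg3g, which argues against such RNA as the main source, and no biological explanation was tested.

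A cluster of 1721 cells with ciliated and secretory markers together had a median of 17472 UMIs, against 2484 in ciliated-like and 10788.5 in secretory-like cells. It held 7.26%, 9.56%, 10.7% and 7.05% of cells in libraries 1 to 4. Pairs caught by chance in 1 droplet were argued against as the whole source, since its share was at least 9.43 times the share expected from loading in every library. Part of the mixed cells may still be such pairs. Of 888 predicted doublets, a number set by the loading rate, 616 lay in mixed clusters when doublets were kept. They made up 21.0% of the 2939 cells there, against 0.234% of ciliated-like and 3.19% of secretory-like cells. Since their number was set in advance, these shares do not show how many mixed cells were pairs. RNA of a ciliated-like and a secretory-like cell added together remained a candidate explanation, since 0% of 11541 genes lay at least 2 times above both classes, against 4.40% of 10818 genes in hillock-like cells. Any cells with levels between those of both classes would also give a low share, so this test cannot tell added RNA from other sources. Cells left stuck together by dissociation stay open, and no biological explanation was tested.

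Mcpt1 had 0 UMIs in library 2, against 38, 61 and 28 UMIs in libraries 1, 3 and 4.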

How the results depend on the processing

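The tests without the listed genes in clustering, with deeper ciliated-like clusters only and without each library in turn were chosen after the data were seen, and the rest were fixed before the data were examined. Of the main values under an alternative, 294 stayed within their counting interval, or within 1.5 times for counts of genes, and 38 moved. Of values for single genes, 3444 stayed, 877 moved without a change of sign and 23 reversed. TMM scaling and a floor of 10 UMIs moved no count of genes apart between libraries, and a pseudocount of 10 CPM reversed no gene but moved 254 of 434 values for single genes, and thinning to 500 UMIs moved 321 of 434. Clustering without the listed genes gave no macrophage-like class, so it has no value for that comparison. TMM scaling of mutant against wild-type cells was not run, because cells could not be tied to samples. Depth per cell had medians of 1625.5, 2432 and 2484 UMIs in T cell-like, macrophage-like and ciliated-like cells. Summed UMIs, which the comparisons used, were fewest in T cell-like cells at 86087, macrophage-like cells at 125998 and neuroendocrine-like cells at 147541, against 18202207 in ciliated-like cells.

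With 1000 UMIs per cell, ciliated-like cells made up 22.3% in place of 24.2%, secretory-like 34.0% in place of 32.1%, basal-like 27.7% in place of 25.4% and mixed clusters 12.9% in place of 11.9%, by construction with shallow cells left out. With doublets kept, the shares were 23.1% ciliated-like, 24.5% basal-like and 14.4% mixed. The secretory-like share was 33.4% at 10% mitochondrial UMIs and 31.3% without the listed genes, and the basal-like share was 23.7% at resolution 2.

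In deeper ciliated-like clusters only, Cfap221 in library 2 was at 8.32 CPM, Cfap54 in library 2 at 2.08 CPM, and Spef2 at 100.2, 189, 248 and 229 CPM in libraries 1 to 4, of which the value in library 3 had not moved. As a mean over cells, which gives shallow cells more weight, Cfap221 in library 2 was at 18.6 CPM, Cfap54 at 113 and 7.13 CPM in libraries 1 and 2, and Spef2 at 224, 306, 276 and 277 CPM in libraries 1 to 4. Their order between libraries was kept for Cfap54 and Spef2 in so far as library 2 stayed lowest for Cfap54 and library 1 for Spef2.

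With each cell thinned to 500 UMIs, log2 ratios reversed in ciliated-like cells for H2-T23 to -0.17, Jag1 to -0.63 and Ttc21b to -0.02, in secretory-like cells for Tubb2b to 0.41, and in basal-like cells for Igtp to 0.08, Irf9 to -0.43 and Nrarp to -1.17. In macrophage-like cells Gbp3 reversed to -1.40, Tgfb1 to -4.00 and mt-Cytb to 0.04, and 13 listed genes in place of 26 were higher in all 4 libraries. With doublets kept, Col6a1 in basal-like cells reversed to 0.62. The cause was not tested.

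Other reversals were all in macrophage-like cells. At resolution 0.5, Ereg was at 0.76 and Lfng at 1.39, and at 10% mitochondrial UMIs Lfng was at 1.45. With variable genes chosen within each library, Clca2 and Hey1 were at 1.12 each, Col4a2 at 4.47, Col6a1 at 5.97, Ereg at 0.50, Lfng at 1.07, Mmp2 at 3.85, Saa3 at 3.34 and Sparc at 5.20, all from negative values. The cause was not tested.

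Genes apart between libraries numbered 381, 217 and 184 in secretory-like, basal-like and ciliated-like cells with at least 400 UMIs, by construction with fewer genes, in place of 973, 736 and 591. Without library 1, 2, 3 or 4, the counts were 623, 545, 526 and 532 in secretory-like cells, 482, 418, 439 and 259 in basal-like cells, and 295, 386, 303 and 376 in ciliated-like cells. A ratio of highest to lowest over fewer libraries is smaller by construction.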

Other observations

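This part reports no test of an explanation, and the values below were chosen for mention after they were seen.

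Hillock-like cells, 523 in all and led by the squamous keratins Krt13 and Krt4, carried wound repair and keratin genes at a higher level than other cells, for 8 of 13 members in all 4 libraries. Ereg was at log2 4.17 (2.58 to 4.55 over libraries), Krt6b at 3.82 and Krt16 at 3.46. The water channel Aqp5 was at 3459 CPM, with a log2 ratio of 3.0. Arginase Arg1 was at 3.56, the interferon-induced Ifit1 at 3.05, the cytokine Il18 at 2.75 and the detoxifying enzyme Aldh3a1 at 2.01. Reg3g was lower there, at -4.91.

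Tuft-like cells, 152 in all, had higher levels of Gpx3 (4.97, on 38 UMIs), the macrophage migration inhibitory factor Mif (3.15), the immunoproteasome subunit Psmb9 (2.97), Il18 (2.77) and the transcription factor Irf1 (2.41). All 8 RNA quality genes were higher in tuft-like cells of each library, with mt-Co2 at 1.32. In 42 neuroendocrine-like cells the anion transporter Slc26a9 was at 5.79 on 17 UMIs, and Fabp5 at 3.35. In 40 T cell-like cells Psmb8 was at 4.07 and B2m, the light chain of class I molecules, at 2.81.

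Some genes separated the 4 libraries into pairs by at least 5-fold over all filtered cells, with values for each library in order. Libraries 1 and 4 were higher for 3 genes, namely Pianp (9.20, 0, 0.0212 and 8.82 CPM), Cntnap2 (2.52, 0, 0.0635 and 3.20 CPM) and Ttr (5.70, 0, 0.148 and 3.06 CPM). Libraries 2 and 3 were higher for 8 genes, including Tpm3-rs7 (3.40, 46.2, 50.6 and 2.71 CPM), Gm21190 (0.388, 13.4, 9.44 and 0.210 CPM), Pnp2 (0.0243, 1.08, 4.02 and 0.0233 CPM) and Slc35g2 (0.315, 2.92, 4.21 and 0.583 CPM). Tpm3-rs7, Gm21190 and Pnp2 have close copies, so their counts are uncertain. Libraries 1 and 3 were higher for 5 genes, including Cytl1 (6.28, 0, 8.11 and 0 CPM), Ccl21a (6.94, 0, 3.05 and 0 CPM) and Mgp (5.24, 0.325, 1.91 and 0.0700 CPM), all leading genes of a cluster of 16 cells. That mixed cluster had 4, 3, 6 and 3 cells in libraries 1 to 4, so these values may rest on few cells, which was not tested. The other pairings had 0 such genes.

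The goblet marker Tff2 in secretory-like cells was at 303, 94.4, 80.4 and 1603 CPM. The pseudogene Rps18-ps6, whose count is uncertain beside its parent gene, was at 0.442, 0.484, 30.1 and 0.198 CPM in the same cells. Skeletal muscle markers summed to 92.0, 48.7, 17.9 and 59.3 CPM over all filtered cells, and fibroblast markers to 29.9, 31.3, 20.3 and 31.0 CPM.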
